A study of Homo sapiens with 3 samples.

How the data were processed

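The study measured mature microRNAs (miRNAs), the short RNAs that repress messenger RNAs, by small RNA sequencing in TU-177, an established cell line from a laryngeal squamous carcinoma. Per the labels' protocols, cells were parted by magnetic sorting on the surface proteins CD133 and CD44, and the series text says that the sorted cells were cultured. There were 3 libraries, 1 of CD133+CD44+ cells, 1 of CD133-CD44- cells and 1 of unsorted cells. Each library was made from total RNA of 3 samples of its group mixed in equal amounts and was sequenced on an Illumina HiSeq 2000, per the series text. The 3 RNA samples of a group cannot be told apart after pooling, so each group has 1 library and no spread between replicates.

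The values are RPM as deposited (reads scaled to a library total of 1e+06), although the column names call them TPM, per the file headers. Every value in every library is a whole multiple of 1 step within a tolerance of 0.001 reads, and the step is the same for every entry of a library, so the values have no length term. The step gave totals of 5246171 reads for CD133+CD44+, 4929147 for CD133-CD44- and 5677317 for unsorted cells, and 100% of values came out as whole reads. All but 360, 322 and 298 of these reads, in the same order, belong to the 1543 listed entries. Per the submitters' processing notes, Bowtie was used with the genome build hg18. The Bowtie version, the miRNA annotation and its version, the counting tool, the handling of strand and the mismatches allowed are not given in the sources used here.

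Names were used as the files give them, without the species prefix, and the suffixes 5p and 3p mark the arm of the hairpin that a mature miRNA comes from. The files hold no coordinates, and the reference annotation used here (GENCODE 29, GRCh38) is of another build than hg18, so no positions are printed. That annotation served only to find which hairpins overlap or neighbour each other. A locus was found for 1107 of 1108 hairpin names.

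Reads that match several near-identical entries are uncertain, because how they were assigned is not given. This holds for close family members such as let-7a and let-7f, miR-1260a and miR-1260b, miR-199a and miR-199b, and miR-151a-5p and miR-151b. It also holds for hairpins on opposite strands of 1 locus, such as miR-7 and miR-3529, miR-203a and miR-203b, miR-24 and miR-3074, and miR-423 and miR-3184.

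With 1 library per group there is no test between conditions, and no difference below has a replicate check. A miRNA was counted as higher or lower by a fixed rule of size, at least 2-fold on the log2(RPM + 1) scale with at least 10 RPM in at least 1 of the 2 libraries compared. The pseudocount of 1 RPM makes these folds smaller than the plain ratios for scarce miRNAs. Folds printed with an interval are plain ratios of RPM with the 95% exact conditional (Clopper-Pearson) interval of the 2 read counts. Intervals of single levels are exact Poisson intervals. Reads without molecular identifiers are not independent molecules, and these intervals and the floors cover counting error only, not differences between cultures, sorts or library preparations. 1 read stood for 0.191, 0.203 and 0.176 RPM in the CD133+CD44+, CD133-CD44- and unsorted libraries. As the limit for a count of 0, 3 reads were used, a one-sided limit that is lower than the upper end of the two-sided Poisson interval of 0 reads. It stood at 0.572, 0.609 and 0.528 RPM in the same order, and 10 RPM stood for 52.5, 49.3 and 56.8 reads.

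The rule had been written for TPM values before the data were examined, and was applied unchanged to RPM. After it was seen that reads could be recovered, an exact binomial test of the reads of 2 libraries was added, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. That test compares the libraries, not the conditions.

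The miRNAs named in the text were chosen by a rule set before the data were examined. For CD133+CD44+ against CD133-CD44-, it took the 12 with the highest and the 12 with the lowest log2 fold change on the scale above, among those with at least 10 RPM in at least 1 of the 2 libraries. For each other comparison it took the 6 highest and the 6 lowest. It also took the 10 with the highest mean over the libraries, the members of the fixed lists with at least 10 RPM in at least 1 library, and up to 6 in each direction among those that stood apart in the CD133+CD44+ library. Outside this rule, miR-150-5p, miR-106a-5p, miR-20b-5p, miR-103b and partners on opposite strands were named after their values were seen.

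27 lists with 243 distinct members were fixed before the data were examined, and 200 members matched an entry by exact name or, failing that, by the older name without the arm. The lists were the let-7, miR-200, miR-29, miR-30, miR-26 and miR-181 families, the families of miR-15 with miR-16, of miR-130 with miR-301 and of miR-148 with miR-152, the miR-34 family with other p53-responsive miRNAs, and the miR-17-92 cluster with its paralogs. Further lists were the clusters of miR-23 with miR-27 and miR-24, of miR-99 with miR-100 and miR-125, of miR-221 with miR-222 and of miR-183 with miR-96 and miR-182, the pluripotency clusters (miR-302 and miR-371), the imprinted DLK1-DIO3 cluster, the chromosome 19 cluster, squamous epithelial miRNAs and miRNAs often raised in cancers (oncomiRs). Markers of other cell types were listed for blood cells, muscle, endothelium, fibroblasts and stroma, neurons, and liver and serum. The last list held entries that share sequence with other small RNAs, such as tRNA and ribosomal RNA. A member was measured with at least 1 RPM in at least 1 of the 2 libraries. For a list with at least 3 measured members, the median log2 fold change was set against the medians of 10000 random lists of the same size, matched on mean level in 10 bins. Members counted as higher or lower in a list are counted whatever the size of the difference, unless a 2-fold difference is named. A list was called apart with a percentile under 2.5 or over 97.5, and the percentile describes these libraries and is not a p-value. Random lists were drawn entry by entry. Several fixed lists hold both arms of a hairpin, hairpins of 1 cluster or near-identical entries, which may move together. For such lists the percentile can look more extreme than separate members would make it. In each comparison, 22 lists had enough members.

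The calls were tested on simulated reads for 302 entries with the real levels and totals. Of the entries simulated 3-fold apart, 100%, 100% and 95.5% were called in CD133+CD44+ against CD133-CD44-, CD133+CD44+ against unsorted and CD133-CD44- against unsorted cells. Of those simulated 6-fold apart, 100% were called in each comparison, and of those simulated 1.5-fold apart or unchanged, 0% were called. Of 200 random lists of miRNAs simulated with equal levels in both libraries, 10%, 6% and 3.5% were called apart in the same order. The first of these lies above what the 2 thresholds imply. The simulated lists hold counting noise alone, so they do not give the rate at which real lists are called apart by chance. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

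Alternatives set before the data were examined were pseudocounts of 0.1 and 10 RPM, minimum levels of 1 RPM, 100 RPM and none, and 3 other scalings of the libraries. The scalings were median ratios, a trimmed mean of log ratios (30% of folds and 5% of levels trimmed) and totals without the 10 most abundant miRNAs. Both arms of a hairpin were also summed, and lists were also run with a minimum of 10 RPM and with random lists not matched on level. Added after the data were seen were the read test, a run without 1 entry of each pair with the same reads on opposite strands, and a run without the members of the other-cell-type lists.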

Results

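Mature miRNAs were profiled in 3 pooled small RNA libraries of TU-177 laryngeal squamous carcinoma cells, 1 of CD133+CD44+ cells, 1 of CD133-CD44- cells and 1 of unsorted cells. CD133 and CD44 are surface proteins used to enrich tumour cells with stem cell properties, and the study labels the double-positive cells as cancer stem cells. The design asks which miRNAs differ between these cells, the double-negative cells and the unsorted line. The libraries held 5246171, 4929147 and 5677317 counted reads in the CD133+CD44+, CD133-CD44- and unsorted cells, in that order, and 968, 935 and 1004 of 1543 entries had at least 1 read. At least 10 RPM was reached by 293, 289 and 302 entries. As each group had 1 library, differences are given as sizes with counting intervals, without a test between conditions.

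A single miRNA, miR-21-5p, which is abundant in many carcinomas, made up 49.8% of the reads in CD133+CD44+ cells, 53.5% in CD133-CD44- cells and 57.5% in unsorted cells. The next in rank, miR-148a-3p, made up 14.8%, 6.34% and 4.26% in the same order. let-7i-5p held 3.42%, 4.71% and 3.73%, and let-7f-5p held 3.20%, 4.35% and 3.57%. miR-205-5p, a miRNA of squamous and basal epithelium, held 0.588%, 1.29% and 1.68%. The others among the 10 most abundant were miR-30d-5p, let-7a-5p, miR-151a-3p and the pair miR-7-5p and miR-3529-3p, whose hairpins lie on opposite strands of 1 locus. The 10 most abundant entries of each library took 83.5%, 80.2% and 80.6% of its reads. Across the 269 entries with at least 10 RPM in every library, Pearson's r of log2 levels was 0.966 between the sorted libraries, 0.963 between CD133+CD44+ and unsorted, and 0.980 between CD133-CD44- and unsorted cells. Entries are not independent replicates.

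The comparison of the sorted populations asks what sets CD133+CD44+ cells apart from CD133-CD44- cells. The muscle miRNA miR-1-3p was 20.5-fold higher in the CD133+CD44+ library (587 against 28.6 RPM, interval of the fold 17.3 to 24.5). miR-151a-5p was 10.3-fold higher (1725 against 167 RPM, interval 9.60 to 11.1) and miR-143-3p, a miRNA of smooth muscle and fibroblasts, was 8.19-fold higher (575 against 70.2 RPM). Among the most abundant miRNAs, miR-148a-3p was 2.33-fold higher and the opposite arm of the same miR-151a hairpin, miR-151a-3p, was 2.54-fold higher. Lower in the CD133+CD44+ library were miR-205-5p, by 2.19-fold (5883 against 12890 RPM), and miR-20a-5p and miR-17-5p of the miR-17-92 cluster, which promotes proliferation, by 2.62-fold and 2.35-fold.

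**Figure D1:**
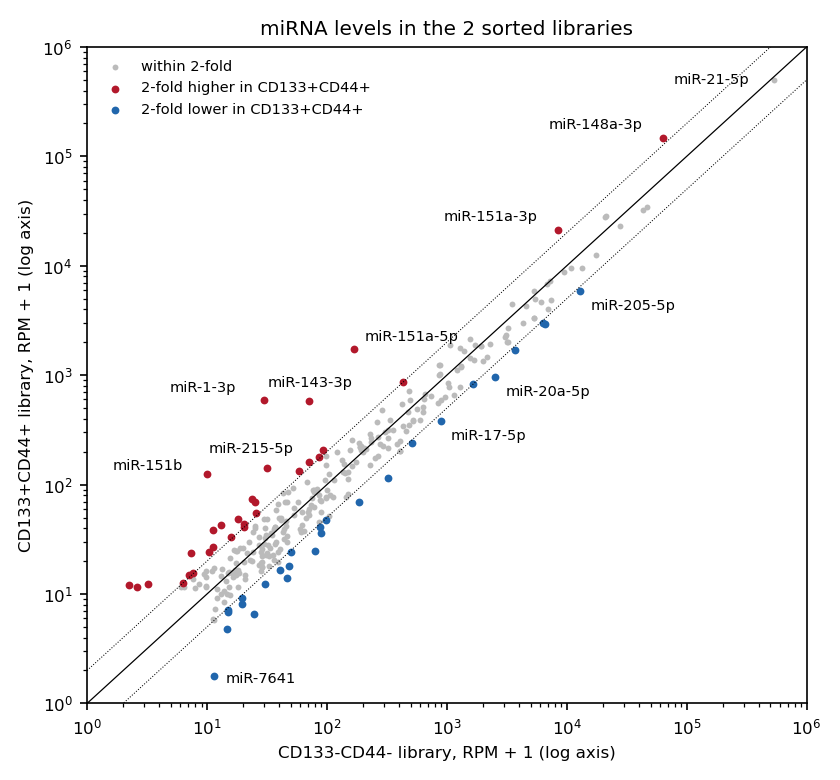
Levels of the 309 miRNAs with at least 10 RPM in at least 1 sorted library, as RPM + 1 on log axes, with the CD133-CD44- library on the x axis and the CD133+CD44+ library on the y axis. The solid line marks equal levels and the dotted lines 2-fold differences; 30 miRNAs lie on or above the upper and 26 on or below the lower dotted line.

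By the rule of size, 30 of 309 miRNAs were higher and 26 were lower in the CD133+CD44+ library, and 253 (81.9%) lay within 2-fold. The median log2 fold change of the 309 was -0.11. Scaling by median ratios, by a trimmed mean or by totals without the 10 most abundant miRNAs moved the fold changes up by a median of 0.15, 0.15 and 0.26 on the log2 scale, and those of scarce miRNAs by less because of the pseudocount. The split into higher and lower then became 36 and 15, 37 and 15, and 45 and 12, so 53.6% of calls were upward with the deposited scaling and 70.6%, 71.2% and 78.9% with the others. All 56 calls also passed the added exact binomial read test with Benjamini-Hochberg adjustment, which found 96 miRNAs higher and 138 lower between these 2 libraries. In each comparison such passing was nearly set in advance by the rule of size and is no separate check. In the simulated reads for this comparison, the read test found 84.8% of entries 1.5-fold apart and 100% of those 3-fold apart.

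Also among the 12 highest were miR-151b (13.8-fold, 124 against 8.93 RPM), which nearly shares its sequence with miR-151a-5p, and miR-184 (9.08-fold, 58 against 6 reads). miR-215-5p, a p53-responsive miRNA, was 4.67-fold higher and the red blood cell miRNA miR-451a was 3.66-fold higher. miR-3690, miR-1291, miR-125b-1-3p, miR-4661-5p and miR-22-5p were 3.21- to 6.46-fold higher. Of these, miR-1291 is on the list of entries that share sequence with other small RNAs. At the other end, miR-7641 had 4 reads in the CD133+CD44+ library and 51 in the CD133-CD44- library, a fold of 13.6 with an interval from 4.99 to 51.7. miR-1307-5p was 4.26-fold lower, miR-16-1-3p 3.54-fold, miR-3940-3p 3.33-fold, miR-33a-3p 3.62-fold and miR-548k 2.82-fold. Both arms of miR-424 were lower, miR-424-5p by 2.81-fold and miR-424-3p by 2.71-fold. miR-675-5p, which is processed from the H19 transcript, miR-942-5p and miR-660-5p were 2.56-, 2.57- and 2.48-fold lower. The counting intervals of these 24 folds all excluded 1, and those of miR-675-5p and miR-942-5p, with lower bounds of 1.97 and 1.89, reached below 2.

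**Figure D2:**
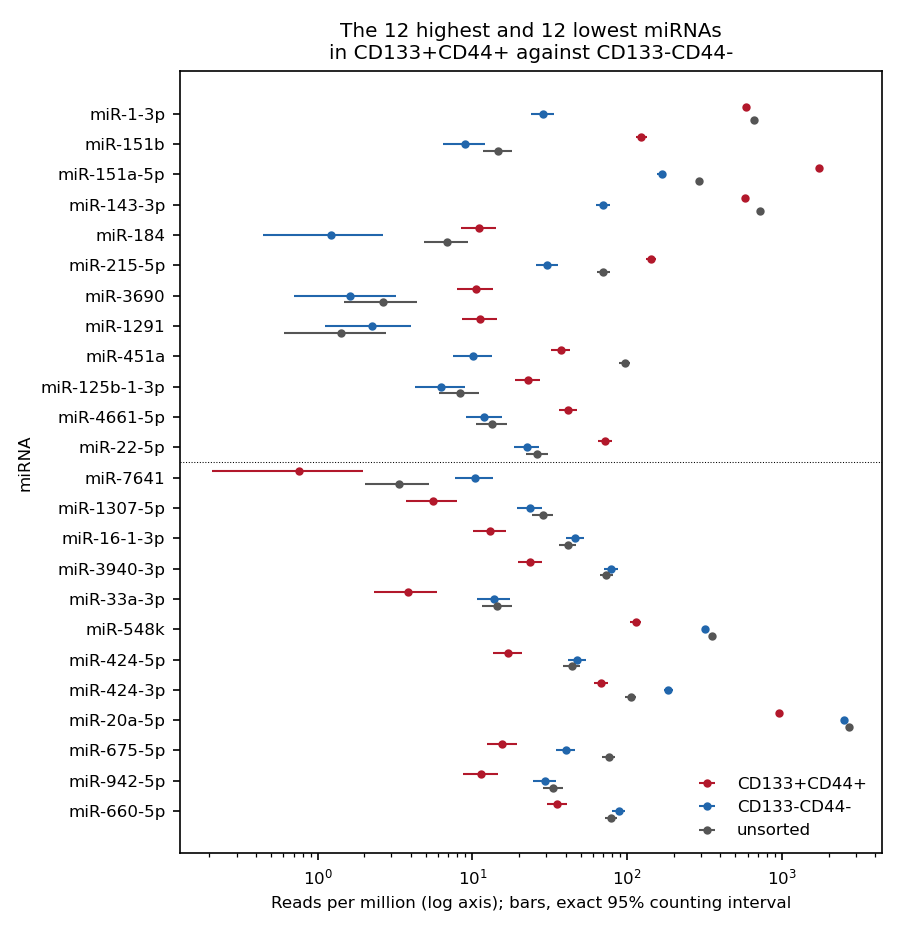
Levels in RPM, on a log axis, of the 12 highest (above the dotted line) and the 12 lowest miRNAs of CD133+CD44+ against CD133-CD44- cells, with the unsorted library beside them. Points are single libraries and bars their exact 95% counting intervals; miR-1-3p and miR-143-3p in unsorted cells lie near the CD133+CD44+ level, and miR-20a-5p in unsorted cells near the CD133-CD44- level.

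Of the 22 lists with at least 3 measured members, 2 stood apart as lower and 4 as higher in the CD133+CD44+ library. Of the miR-17-92 cluster and its paralogs, 11 of 12 members were lower, with a median of -0.76 (log2) and a percentile of 0.07 among random lists. By at least 2-fold, 5 of the 12 were lower, and 4, 4 and 3 with the other scalings. The 5 include the scarce miR-106a-5p (3 against 25 reads) and miR-20b-5p (7 against 23 reads), which are close in sequence to miR-17-5p and miR-20a-5p. miR-93-5p stood at 823 against 1647 RPM, miR-19b-3p was 1.86-fold lower and miR-92a-3p 1.54-fold, while miR-363-3p was 1.59-fold higher. All 7 measured members of the miR-15 and miR-16 family, known to restrain the cell cycle, were lower, with a median of -0.71 and a percentile of 0.51, 1 of them (miR-424-5p) by at least 2-fold. miR-15b-5p was 1.64-fold lower and miR-16-5p 1.32-fold lower. The other scalings kept 11 of 12 members of the first list lower, and 7, 7 and 6 of 7 of the second, with medians from -0.61 to -0.49 and from -0.57 to -0.47.

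Lists of other cell types were among those higher in the CD133+CD44+ library. All 4 measured muscle members were higher, with a median of 1.58 and a percentile of 99.95, and all 7 fibroblast and stromal members were higher, with a median of 1.27 and a percentile of 99.97. At least 2-fold were 3 of the 4 and 4 of the 7. Beyond miR-1-3p and miR-143-3p these members were scarce, and with a minimum of 10 RPM both lists had under 3 members and could not be ranked. The 7 stromal members were both arms of miR-143, of miR-145 and of miR-199a, with miR-199b-5p, so they were not 7 separate hairpins. miR-145-5p stood at 8.39 against 2.43 RPM, miR-133a-3p at 4.38 against 1.22 RPM, and miR-206 at 18 reads against 1 read. The blood cell list had 3 of 4 members higher, 2 by at least 2-fold, and a percentile of 97.52, at the threshold, and miR-486-5p was 1.32-fold lower. Its median of 0.81 went to 1.16 and 0.16 with pseudocounts of 0.1 and 10 RPM, and the call was lost with both. The call was also lost with the 3 other scalings, where miR-150-5p (5 against 3 reads) passed the minimum of 1 RPM as an additional member, while the median of the same 4 members went up to 0.90, 0.90 and 0.96. Of the imprinted DLK1-DIO3 cluster, 12 of 14 members were higher, 4 by at least 2-fold, with a median of 0.64 and a percentile of 99.66. Of the 4, miR-381-3p (159 against 69.8 RPM) was 2.28-fold higher, and the others were scarce, under 10 RPM in both libraries. miR-409-3p (10.7 against 5.07 RPM) was 2.10-fold higher as a plain ratio, but lay under 2-fold with the pseudocount. With a minimum of 10 RPM, 3 members of the cluster remained, with a median of 0.94 and a percentile of 92.1, and the call was lost. Of random lists simulated with counting noise alone, 10% were called apart in this comparison, which is not the chance rate for the real lists.

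**Figure D3:**
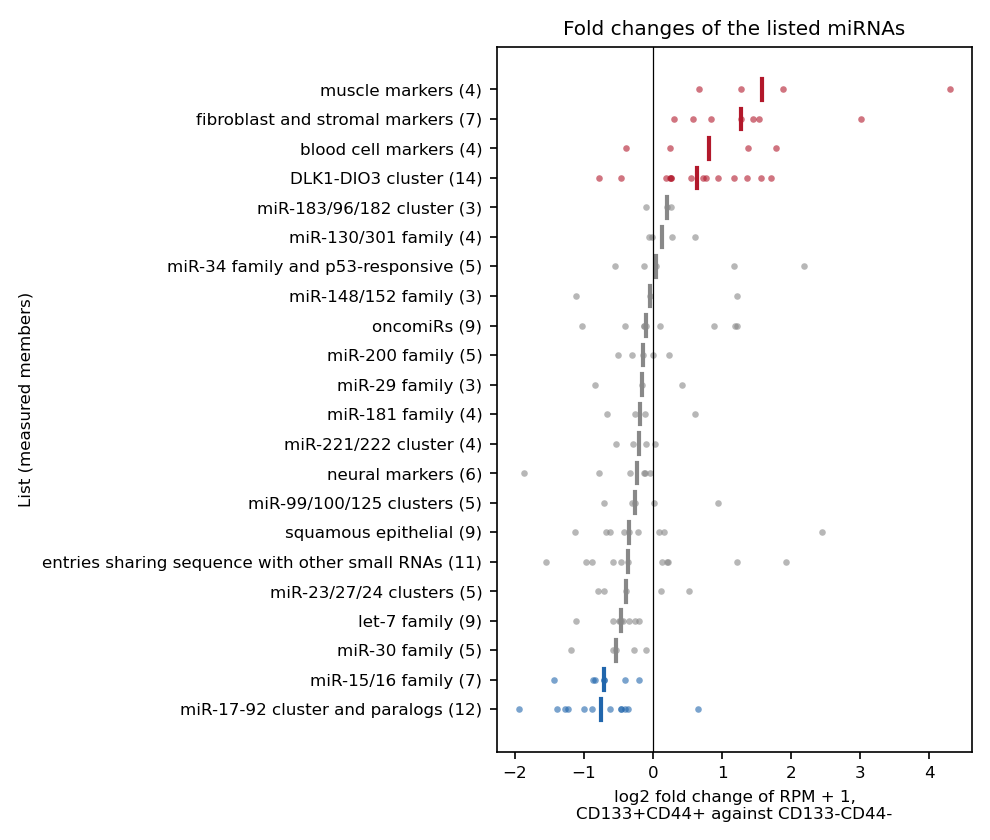
log2 fold changes (RPM + 1) of the measured members of 22 lists, CD133+CD44+ against CD133-CD44-, with a point per miRNA and a bar at the list median. Red and blue mark the 4 lists apart as higher and the 2 apart as lower; under other scalings the medians of the oncomiR, miR-200, miR-29, miR-181 and neural lists change sign, as do those of the lists of miR-148 with miR-152, of miR-221 with miR-222 and of miR-99 with miR-100 and miR-125.

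The other lists lay within the range of random lists. All 9 let-7 members, which are high in differentiated cells, were lower in the CD133+CD44+ library, with a median of -0.46 and a percentile of 9.13, and 9, 9 and 8 of 9 stayed lower with the other scalings. let-7c-5p was 2.17-fold lower and let-7a-5p 1.41-fold lower. All 5 miR-30 members were lower (median -0.54, percentile 10.0), among them miR-30b-5p by 2.28-fold, and 4 of 5 stayed lower with each other scaling. Of the squamous epithelial miRNAs, 6 of 9 were lower (median -0.35, percentile 14.4), including miR-205-5p, miR-203a-3p by 1.61-fold and miR-31-5p by 1.54-fold, against miR-184 at 9.08-fold higher. The miR-200 family, which maintains the epithelial state, had 3 of 5 members lower (median -0.14, percentile 54.2), a median that turned to 0.01, 0.01 and 0.12 with the other scalings. miR-200c-3p stood at 4951 against 5463 RPM and miR-200b-3p was 1.43-fold lower. In the miR-148 and miR-152 family, miR-148a-3p was 2.33-fold higher and miR-148b-3p 2.18-fold lower. Its median of -0.05 (percentile 70.8) turned positive with each other scaling.

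The oncomiR list had 4 of 9 members higher (median -0.10, percentile 54.8), a median that also turned positive with each other scaling. miR-135b-5p was 2.30-fold higher, miR-10b-5p 1.85-fold higher and the hypoxia-responsive miR-210-3p 2.09-fold lower. The miR-34 and p53-responsive list (3 of 5 higher, percentile 63.8), the miR-130 and miR-301 family (2 of 4, 74.2) and the miR-183, miR-96 and miR-182 cluster (2 of 3, 83.6) had medians of 0.04, 0.13 and 0.20. The miR-23, miR-27 and miR-24 clusters (2 of 5 higher, percentile 32.5) had a median of -0.39, and the entries sharing sequence with other small RNAs (5 of 11, 9.84) one of -0.36. The clusters of miR-99 with miR-100 and miR-125 (2 of 5 higher, percentile 37.9) and of miR-221 with miR-222 (1 of 4, 42.3), and the miR-181 (1 of 4, 37.6), miR-29 (1 of 3, 42.5) and neural lists (0 of 6, 27.2), had medians of -0.25, -0.20, -0.18, -0.16 and -0.23. Each of these 5 medians turned positive with totals without the 10 most abundant miRNAs. The miR-26 family and the endothelial list had 2 measured members each and were not ranked. miR-126-3p, the endothelial miRNA, stood at 862 against 426 RPM and was higher by the rule of size. The other arm, miR-126-5p, was lower, with a log2 fold change of -0.37. The liver and serum miRNA miR-122-5p stood at 39.6 against 35.7 RPM. The pluripotency and chromosome 19 lists had 0 measured members in each comparison.

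The comparison of CD133+CD44+ with unsorted cells asks how the double-positive cells differ from the line they came from. miR-151b and miR-151a-5p were 8.45- and 5.90-fold higher in the CD133+CD44+ library, miR-132-3p 3.61-fold, miR-148a-3p 3.47-fold and miR-151a-3p 3.31-fold. miR-1291, an entry that shares sequence with other small RNAs, was 7.98-fold higher (59 against 8 reads). The lowest was miR-4521, at 51.1 against 826 RPM, 16.2-fold lower (interval 14.3 to 18.4). The stromal miRNAs miR-199b-5p and miR-145-5p were 8.39- and 6.30-fold lower, miR-1307-5p 5.16-fold and miR-675-5p 4.87-fold. miR-127-3p of the DLK1-DIO3 cluster stood at 9.72 against 58.3 RPM. miR-1-3p and miR-143-3p, far apart between the sorted libraries, stood at 587 against 663 RPM and at 575 against 717 RPM.

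By the rule, 27 of 322 miRNAs were higher and 50 lower in the CD133+CD44+ library, with a median log2 fold change of -0.25. The other scalings moved the fold changes up by a median of 0.20, 0.17 and 0.25 and gave 39 and 35, 37 and 36, and 42 and 34, so the share of upward calls went from 35.1% to 52.7%, 50.7% and 55.3%. Of the miR-17-92 cluster and its paralogs, 11 of 12 members were lower with every scaling (median -0.89, percentile 0.13). All 7 miR-15 and miR-16 members were lower (median -1.14, percentile 1.77), 6 of 7 with each other scaling. All 8 fibroblast and stromal members were lower with every scaling (median -1.19, percentile 0.17). No list stood apart as higher. The neural list (7 of 7 lower, percentile 3.35), the blood list (3 of 4, 22.3), the muscle list (4 of 5, 15.0) and the DLK1-DIO3 cluster (10 of 18, 43.2) were within the range of random lists. The read test found 101 higher and 170 lower between these libraries, including all 77 calls.

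CD133-CD44- cells were compared with unsorted cells to show how the double-negative cells differ from the line. Muscle and stromal miRNAs were lower in the CD133-CD44- library. miR-1-3p was 23.2-fold lower (28.6 against 663 RPM, interval 19.6 to 27.6), miR-143-3p 10.2-fold and miR-145-5p 21.7-fold. miR-127-3p was 22.1-fold lower, miR-133a-3p 18.5-fold (6 against 128 reads), and miR-206 had 1 read against 68. Higher in the CD133-CD44- library were miR-1260b, by 2.76-fold (231 against 83.7 RPM), and miR-1260a, by 2.55-fold, 2 entries that share sequence with tRNA, with miR-7641, miR-320d, miR-4791 and let-7f-1-3p at 2.18- to 3.09-fold.

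By the rule, 6 of 309 miRNAs were higher and 19 lower in the CD133-CD44- library, and 284 (91.9%) lay within 2-fold. All 5 muscle members (median -3.41, percentile 0.00) and all 8 stromal members (median -2.34, percentile 0.00) were lower, with 3 of 4 blood members (median -1.22, percentile 0.26) and 12 of 17 DLK1-DIO3 members (median -0.52, percentile 1.28). These counts were equal with every scaling. The miR-148 and miR-152 family stood apart as higher (2 of 3 members, median 0.44, percentile 98.96), while the miR-17-92 list (10 of 12 lower, median -0.12, percentile 21.3) and the miR-15 and miR-16 family (4 of 7 lower, percentile 21.1) did not stand apart. Without the members of the other-cell-type lists, an alternative added after the data were seen, 9 miRNAs were lower instead of 19. The read test found 75 higher and 123 lower, including all 25 calls.

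Taking the libraries together, the CD133+CD44+ library was at least 2-fold higher than both others for 20 of 325 miRNAs and at least 2-fold lower than both for 20. Highest by this measure were miR-151b, miR-151a-5p, miR-1291 (which shares sequence with other small RNAs), miR-3690, miR-132-3p and miR-4661-5p. Lowest were miR-1307-5p, miR-16-1-3p, miR-33a-3p, miR-3940-3p, miR-548k and miR-20a-5p. The CD133-CD44- library was higher than both others for 1, miR-7641, and lower for 10, among them miR-1-3p, miR-143-3p and miR-451a. The unsorted library was higher for 10, among them miR-4521 and miR-127-3p, and lower for 3, which were miR-1260a, miR-1260b and miR-4791. Independent lists of the same sizes would share 2.65 higher and 3.19 lower miRNAs for the CD133+CD44+ library, 0.53 and 0.86 for the CD133-CD44- library, and 3.10 and 0.27 for the unsorted library. The counts above these values are not particular to 1 library. In each case the comparisons share a library, and part of the excess may come from that, which these values leave out. In 100 simulations of equal libraries at most 1 miRNA stood apart, but they hold counting noise alone and no difference between separate preparations. With the other scalings, 12, 12 and 10 miRNAs were lower in the CD133+CD44+ library than in both others.

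Unsorted cells lay between the sorted libraries for 26 of the 56 miRNAs called between these (46.4%). The CD133-CD44- library lay between the other libraries for 56 of 77 calls (72.7%), and the CD133+CD44+ library for 19 of 25 (76.0%).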

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

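The read test and the run without other-cell-type lists were chosen after the data were seen. There were no replicates, so no leave-one-out run was made. No paired analysis was possible because each group has 1 library. Counts of miRNAs moved with the call, the pseudocount, the minimum level and the scaling, and are given in the order CD133+CD44+ against CD133-CD44- (higher, lower), CD133+CD44+ against unsorted, and CD133-CD44- against unsorted. With a pseudocount of 10 RPM, 16 and 14, 15 and 29, and 1 higher were called. With a minimum of 1 RPM or none, 56 and 44, 41 and 77, and 14 and 44 were called, and with 100 RPM 12 and 10, 11 and 14, and 1 and 4, as fewer entries were tested. The read test gave 96 and 138, 101 and 170, and 75 and 123. Scaling by median ratios and by a trimmed mean left 15 lower in the first comparison each, and totals without the 10 most abundant left 12 lower there and gave 42 higher in the next. Without other-cell-type lists, 9 were lower in the last. Summing arms, a pseudocount of 0.1 RPM and leaving out entries with the same reads on opposite strands kept each count within 1.5 times.

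miRNAs apart from both other libraries numbered 10 higher and 8 lower for CD133+CD44+ with a pseudocount of 10 RPM, and 7 and 6 with a minimum of 100 RPM. Those lower numbered 12, 12 and 10 with the other scalings. For CD133-CD44- they numbered 0 and 3 with the pseudocount of 10 RPM, 3 and 17 with a minimum of 1 RPM or none, 0 and 3 with 100 RPM, 0 higher with totals without the 10 most abundant, and 4 lower without other-cell-type lists. For unsorted cells 1 was lower with the pseudocount of 10 RPM, 7 with a minimum of 1 RPM or none, 1 and 1 with 100 RPM, 5 lower with each scaling, and 3 higher without other-cell-type lists. The CD133-CD44- library lay between the others for 88.0% of 25 calls with a minimum of 100 RPM. Of the lists, 2 instead of 6 stood apart with a minimum of 10 RPM, where muscle, stromal and blood lists had under 3 members and the DLK1-DIO3 median was 0.94 (percentile 92.1). The blood list's median of 1.16 and 0.16 with pseudocounts of 0.1 and 10 RPM, and of 0.35, 0.35 and 0.40 with the scalings, where miR-150-5p (5 against 3 reads) entered as an added member, no longer stood apart. On the same 4 members the scalings gave 0.90, 0.90 and 0.96. The cause was not tested for values without one named. Of 160 fold changes of named miRNAs, 14, 14 and 22 turned sign with the scalings, each from under 2-fold, and 92, 93 and 67 moved by no more than their counting error. Of 66 past 2-fold, 0 reversed, and 66 and 45 stayed so with pseudocounts of 0.1 and 10 RPM, and 61, 61 and 59 with the scalings. Depth limits entries near 10 RPM, where a count is about 50 reads.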

Other observations

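The tests on arms and neighbours were set before their results were seen; those on family members, outside RNA, serum, miR-151a and opposite strands were chosen afterwards. Members of 1 family lay apart in places. Within the miR-30 family, miR-30b-5p was 2.28-fold lower in the CD133+CD44+ library while miR-30a-5p stood at 8797 against 9448 RPM. Within the miR-148 and miR-152 family, miR-148a-3p and miR-148b-3p lay on opposite sides (2.33-fold higher and 2.18-fold lower) and miR-152-3p stood at 313 against 325 RPM. The small differences of miR-30a-5p and miR-152-3p change sign with the other scalings. In the miR-99, miR-100 and miR-125 clusters, miR-99a-5p was 1.95-fold higher, with 42.0 RPM in CD133-CD44- and 147 RPM in unsorted cells, and miR-125a-5p was 1.63-fold lower. miR-100-5p stood at 6865 and 6805 RPM in the sorted libraries and at 3819 RPM in unsorted cells. miR-4521 stood at 826 RPM in unsorted cells against 51.1 and 103 RPM in the CD133+CD44+ and CD133-CD44- libraries.

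A first pattern concerns the fold changes between the sorted libraries as a whole. If they came from the amount of the hairpin, its arms would move alike. Over 66 hairpins, the arms' log2 fold changes differed by a median of 0.54, against 0.56 in random pairings (percentile 38.98). Counting alone gave 0.09, and 42 pairs had 1 direction. The 66 include miR-203a with miR-203b and miR-423 with miR-3184, which lie on opposite strands of 1 locus and may hold the same reads. Neighbouring hairpins under 10 kb apart differed by 0.52 over 58 pairs, against 0.50 at random (percentile 56.8). Only names with a single locus were used, so entries such as miR-92a-1-5p, miR-24-2-5p and miR-16-1-3p stood for their hairpins in place of miR-92a-3p, miR-24-3p and miR-16-5p. Differences between arms therefore enter the comparison of neighbours. Arms and neighbours both differed by more than counting alone gave (0.07 for neighbours), which argues against shared precursor amounts as the only source. A percentile inside the range of random pairings cannot exclude a shared part, which stays open. The rank correlation (Spearman's rho) was 0.27 over arms and -0.03 over neighbours, and 37 of the 58 neighbour pairs had 1 direction. Family members of different hairpins differed less than random pairs over 88 pairs (percentile 0.14), many of them of let-7. With 1 pair per family the percentile was 8.09, not under 2.5, and requiring both was decided after the 2 values were seen. Against unsorted cells, the percentile with 1 pair per family was 0.30 for CD133+CD44+ and 2.35 for CD133-CD44-, both under 2.5. Over all pairs it was 1.215 and 4.17, so only CD133+CD44+ against unsorted cells was under 2.5 both ways. A change tied to mature sequence, which may arise in library preparation or in the cells, therefore stays open, as do effects of sorting and pooling. Reads shared among near-identical family members, whose assignment is not given, could also make their fold changes alike.

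A second pattern is the low level of muscle and stromal miRNAs in the CD133-CD44- library, which may reflect RNA or cells of another kind in the other libraries. If 1 outside source in fixed proportions were behind it, all members would stand in 1 ratio between CD133+CD44+ and unsorted cells. miR-1-3p and miR-143-3p stood at ratios of 0.89 and 0.80, and the 6 others from 0.12 to 0.31. The intervals of all 7 others failed to meet that of miR-1-3p, but the test as written asked for more than 2-fold apart, which 3 of 7 met, under the majority it required, so it decides nothing. For the difference between the sorted libraries, serum carried over from the medium was predicted to raise miR-122-5p and miR-486-5p at least 2-fold in CD133+CD44+. Their upper bounds for the ratio were at most 1.37, so this was not met, although miR-451a was 3.66-fold higher. Against unsorted cells, miR-122-5p was lower in the CD133-CD44- library (ratio 0.49, interval 0.41 to 0.59) and miR-486-5p was not (1.14, interval 1.01 to 1.29). As these miRNAs did not move alike, they may not track 1 serum source, and serum stays open for both differences. A real difference between the sorted populations stays open and untested.

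A further pattern is miR-151a-5p, 10.3-fold higher in the CD133+CD44+ library where its opposite arm miR-151a-3p was 2.54-fold higher. The folds differed 4.06 times, the largest difference among the 66 hairpins, which argues against more of the hairpin alone. Reads moved to miR-151a-5p from miR-151b would leave miR-151b lower, and it was 13.8-fold higher (interval 10.2 to 19.2). As the 2 entries nearly share their sequence and may hold the same reads, that fold is no independent check. What argues against a different split is that miR-151b had 8.93 RPM in CD133-CD44- cells. That is too little to supply the rise of miR-151a-5p from 167 to 1725 RPM. The sum of both entries, 10.5-fold higher, was examined first and decides nothing, as miR-151b held at most 7.16% of the level of miR-151a-5p. miR-151a-5p was 8.08%, 1.99% and 4.54% of miR-151a-3p in CD133+CD44+, CD133-CD44- and unsorted cells. Arm-specific processing or stability, and capture of 1 sequence that differs between preparations, may each account for it and were not tested.

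Of 10 pairs of facing arms on opposite strands of 1 locus, 8 had values within 5% of each other in all libraries, such as miR-7-5p and miR-3529-3p (28559 and 28173 RPM in CD133+CD44+ cells), while 2 of 1764 other pairs of entries with at least 1000 RPM did. This is consistent with reads counted on both strands, and the second entries of such pairs, with miR-103b, held 3.95%, 3.60% and 3.47% of reads. The test was rewritten after a first version, which asked that all near-equal abundant pairs lie on opposite strands, gave 6 of 8 and decided nothing.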
